A study of Arabidopsis thaliana with 27 samples.

How the data were processed

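Whole Arabidopsis thaliana plants of 3 genotypes were compared under 3 conditions. The genotypes were the wild type (WT), a mutant labelled uggt2 and a mutant labelled mrpl1. The conditions were a control, 900 µM zinc (Zn) and 200 nM elf18, a peptide from the start of the bacterial elongation factor Tu that plants sense through the receptor EFR. Each of the 9 groups held 3 libraries, 27 in all. The samples marked CK in the labels were taken as the control. The labels spell the peptide efl18, which was taken as elf18. Among the treatment labels, only that of the elf18 samples also names a medium (ms). Changes with elf18 against control may therefore include a difference in medium. The labels do not say whether the 3 libraries of a group came from separately grown plants, so the spread between them may be partly technical. Per the labels' protocols, messenger RNA was purified from total RNA and libraries were built with a SMARTer kit. The labels do not say whether the reads kept their strand, so a gene could not be told apart from a partner on the opposite strand.

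The deposited table holds expected (estimated) counts per gene for 27628 gene identifiers, as the authors made them. Per the submitters' processing notes, Trimmomatic 0.39, FastQC 0.11.9, HISAT2, featureCounts 1.6.3 and DESeq2 were used, without a stated role or order. Of the deposited values 3.2% were not whole, so all were taken to be expected counts and rounded to whole numbers before any test. How reads shared between near-identical genes were divided is not stated, and values of such genes, small heat-shock genes and chloroplast genes present in a pair of copies among them, are uncertain for that reason. The genome build the authors used is not stated. Gene names and neighbours were therefore taken from the RefSeq annotation of assembly TAIR10.1, in which 27420 of the 27628 identifiers had a locus, and no coordinates are given. The 208 identifiers without one were 120 mitochondrial and 88 chloroplast genes, used under their deposited identifiers.

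Library totals ran from 13.4 to 22.2 M counts. Counts of genes were modelled with edgeR 4.0.16 in R 4.3.3. Genes with too few counts were removed with filterByExpr by group, which left 21438. Library sizes were scaled by the TMM method, and the quasi-likelihood F test was run with robust estimation on a model with a mean for each of the 9 groups, with 18 residual degrees of freedom. There were 16 contrasts. Of these, 12 compared a pair of groups (each treatment with control within a genotype, and each mutant with WT under each condition) and 4 were interactions, the response to a treatment in a mutant minus the response in WT. P-values were adjusted by the Benjamini-Hochberg method within a contrast, with a threshold of 0.05, and a second count required a log2 change of at least 1 in size. Values per group are CPM (counts scaled to a common library size, on TMM-scaled totals) as mean ± SD over 3 libraries. Log2 changes are given ± SE, taken as the log2 change divided by the square root of its F statistic. All adjusted p-values for genes come from edgeR's quasi-likelihood test, and those for lists from camera in limma 3.58.1.

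There were 29 gene lists. Of these, 27 were written out by gene (526 members) and 2 held the mitochondria-encoded and chloroplast-encoded genes. They were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists within a contrast, and again with the correlation estimated from the residuals. Members were counted as risen or fallen by the p adjusted over all genes, and by a p adjusted over the list alone. The lists, the model, the contrasts, the alternatives and the rule for naming genes were fixed before the data were examined. By that rule a gene had to pass the threshold, reach a mean of 5 CPM in a compared group, have every library of one group above every library of the other, and have a symbol. In the 4 main comparisons (each treatment in WT, each mutant under control), the 6 largest rises and 6 largest falls were taken, with the 3 smallest p-values from each list that passed its test or had at least 1 in 3 members past it. In the other comparisons of a pair of groups the 3 largest rises and falls were taken, and in each interaction the 4 smallest p-values in each direction. The genes taken as the targets of the mutants, and EFR, FRK1, PR1, BIP3, AOX1A, ZIP4 and IRT1, were taken whether or not they passed. Only some of the genes so selected are named. Lists of clock genes, mitochondrial ribosomal protein genes and DUF295 genes, and single genes described as such, were chosen after values had been seen.

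The tests were first run on simulated data with known changes. These data used the means of the WT control libraries and the library sizes and estimated spread of all 27 libraries. In the WT Zn group 200 genes were changed, 50 at each of 4 fold sizes. The real comparison called far more genes (9941 for Zn in WT), so the shares below may differ there. The edgeR step ran on 20984 simulated genes. For Zn against control in WT it recovered 70% of the genes changed 1.25-fold, 96% of those changed 1.5-fold, and 100% of those changed 2-fold and 4-fold, and it called 7 genes that had not been changed. DESeq2 1.42.0 recovered the same shares and called 6 unchanged genes.

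Results were recomputed with RLE size factors, without the low-count filter, with the DESeq2 Wald test, with only the compared groups in the fit, with the replicate number as a block, without organelle-encoded genes, with each library left out in turn, and, for lists, with the estimated correlation. For a gene with 0 counts in every library of a group, a fold is given as a bound, with 3 counts per library as the floor. For a gene with 1 to 3 counts in a group, only CPM is given. Floors and bounds cover counting error only, since reads without molecular identifiers are not independent molecules.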

Results

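Transcript levels were measured by RNA sequencing in whole Arabidopsis plants of 3 genotypes, each kept under a control condition, treated with excess zinc (Zn), or treated with elf18, a bacterial peptide that triggers immune responses. Each of the 9 combinations had 3 libraries. Totals per library ran from 13.4 M counts (WT Zn replicate 1) to 22.2 M (mrpl1 control replicate 1), and 21438 genes had enough counts to be tested. The common coefficient of variation between libraries of a group, which edgeR calls biological, was 4.38%. The libraries of a group may not come from separately grown plants. P-values and counts of changed genes below therefore may not measure the spread between plants. WT Zn replicate 1 stood apart from the other libraries of its group (chi-square per degree of freedom 9.91 and 9.13, against 2.11 between the others), as did WT elf18 replicate 1 (5.8 and 4.39, against 2.15). Group values below are mean CPM ± SD and log2 changes are ± SE, with 3 libraries per group. Where single genes are called the largest rises or falls, this is among all genes that met the rule for naming genes, not within a list. Counts of list members adjusted over the list alone are given where they differed from those over all genes tested. Of 242 list tests that passed with the preset correlation, 142 passed with an estimated correlation.

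The genes taken as the targets of the mutants were examined first. EBS1 (AT1G71220), which encodes the glucosyltransferase that tags misfolded glycoproteins in the endoplasmic reticulum (ER), was lower in uggt2 under every condition. It stood at 29.8 ± 0.91 CPM in uggt2 and 69.4 ± 1.9 CPM in WT under control, a log2 change of -1.22 ± 0.10 (adjusted p = 1.8e-09). The changes were -1.47 ± 0.10 under Zn (adjusted p = 5.6e-11) and -1.05 ± 0.09 under elf18 (adjusted p = 1.2e-08). Single uggt2 libraries held 28.7 to 44.5 CPM and WT libraries 67.2 to 101 CPM, so transcript of this gene was reduced and not absent. AT2G42710, which encodes a mitochondrial ribosomal protein of the L1 family and was taken as the gene behind the label mrpl1, was higher in the libraries labelled mrpl1. Its levels were 45.6 ± 1.5 CPM in mrpl1 and 21.6 ± 1.1 CPM in WT under control (log2 change 1.08 ± 0.07, adjusted p = 6.9e-26), with changes of 0.99 ± 0.07 under Zn (adjusted p = 5.5e-23) and 1.53 ± 0.07 under elf18 (adjusted p = 1.4e-37). Single libraries held 44 to 63.2 CPM in mrpl1 and 20 to 27.8 CPM in WT. This goes against a loss of all transcript from the gene, but counts per gene cannot show whether transcripts of either target are full-length. Every direction given below for mrpl1 is that of the libraries labelled mrpl1. In mrpl1, EBS1 did not pass the test against WT under any condition (adjusted p = 0.31 under control).

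**Figure D1:**
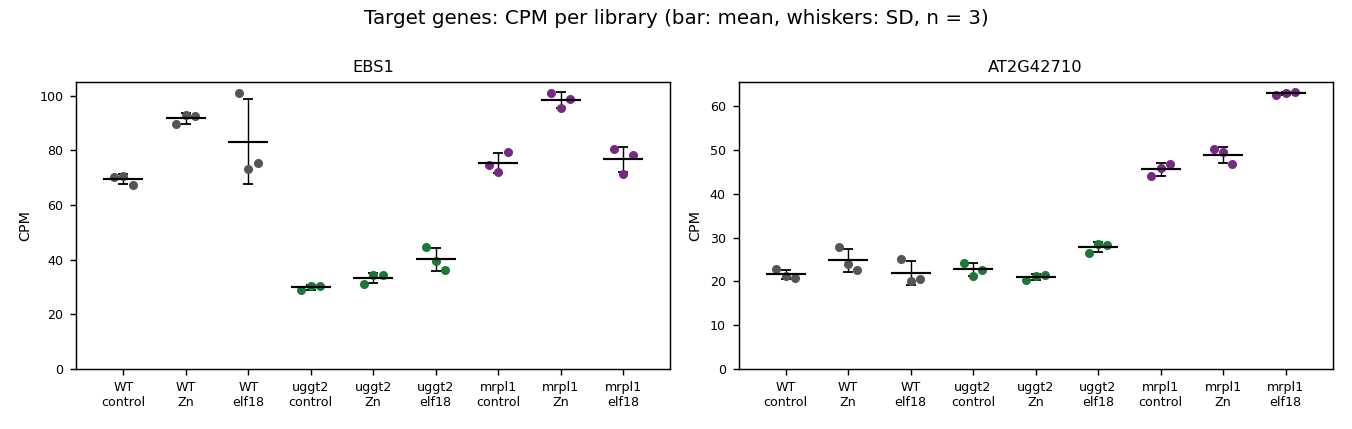
Level of EBS1 and AT2G42710 in CPM in each of the 27 libraries, by genotype and condition, with points for libraries and bars for the mean and SD of 3 libraries. EBS1 sits at 28.7 to 44.5 CPM in uggt2 and at 67.2 CPM or more in WT, and AT2G42710 at 44 CPM or more in mrpl1 and at most 28.6 CPM in the other genotypes.

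Transcripts encoded in the organelles made up unequal shares of the libraries. Chloroplast-encoded genes held 0.617 ± 0.31% of counts in WT Zn and 0.51 ± 0.037% in uggt2 elf18, and between 0.0522% and 0.119% in the other 7 groups. Mitochondria-encoded genes held 0.0397 ± 0.018% and 0.0418 ± 0.0047% in the same pair of groups, and 0.00639% to 0.0148% elsewhere. WT Zn replicate 1 had the largest chloroplast share, 0.972%.

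**Figure D2:**
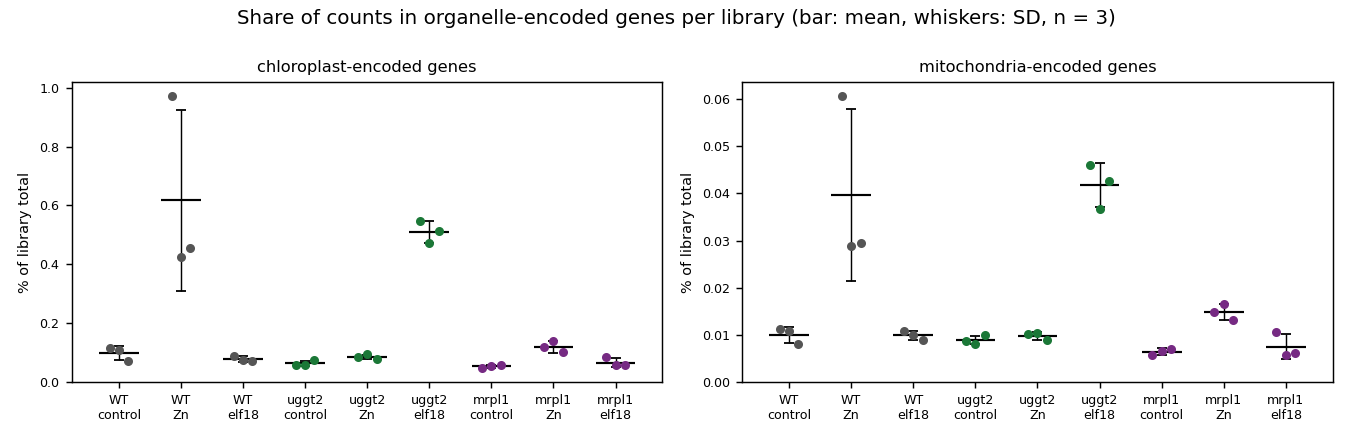
Share of counts, in percent, from chloroplast-encoded and mitochondria-encoded genes in each library, by group, with points for libraries and bars for group means. The WT Zn and uggt2 elf18 groups, with chloroplast means of 0.617% and 0.51%, stand above the other 7 groups, whose means are at most 0.119%.

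The response of WT to Zn shows how wild-type plants react to an excess of the metal. IRT1, the root transporter that takes up iron and also zinc, rose from 4.4 ± 0.37 to 106 ± 6.2 CPM (log2 change 4.59 ± 0.08, adjusted p = 2.8e-66). FRO2, the ferric reductase of the root surface, rose from 3.54 ± 0.26 to 63.6 ± 2.7 CPM (4.17 ± 0.11, adjusted p = 3e-54). Transcription factors of the iron-deficiency response rose with them, BHLH100 by 4.03 ± 0.12, bHLH38 by 3.76 ± 0.15 and bHLH39 by 3.54 ± 0.13, as did CYP82C4 by 4.35 ± 0.16. Of 26 measured iron-deficiency genes 25 rose (median log2 change 1.79, adjusted p = 7.1e-87 by camera). IRT3, a zinc transporter of the zinc-deficiency regulon, fell from 17.2 ± 0.87 to 2.75 ± 0.28 CPM (-2.65 ± 0.13, adjusted p = 3e-33). That list of 8 measured genes did not move as a set (adjusted p = 0.89), and its median of 0.01 and mean of -0.03 had opposite signs. NAS2, a nicotianamine synthase counted in it, rose by 2.37 ± 0.21. ZIF1, which loads the zinc chelator nicotianamine into vacuoles, rose from 76.8 ± 4.2 to 219 ± 4.4 CPM, while 6 of 17 zinc export and chelation genes rose and 8 fell (7 rose when adjusted over the list alone; adjusted p = 0.32, with the median of 0.01 and mean of -0.13 opposite in sign).

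Salicylic acid and jasmonate genes fell as sets in Zn-treated WT, with most members not past the test. PR1, a marker of salicylic acid signalling, stood at 3.83 ± 0.29 CPM under control and had no count in any WT Zn library, which makes it at least 18.5-fold lower with a floor of 3 counts per library. Among 21 salicylic acid genes 7 fell (median -0.42, adjusted p = 0.011). Outside that list, the largest falls among all genes that met the rule were in PCC1 (-5.86 ± 0.39), SAG13 (-4.51 ± 0.27), AIG1 (-3.71 ± 0.26) and TAT3 (-2.82 ± 0.31), with CYP71A12 at -2.38 ± 0.14. Jasmonate genes fell in 11 of 27 cases and rose in 3 (median -0.08, adjusted p = 0.0075), and VSP2, a jasmonate-induced storage protein gene, dropped from 14.2 ± 1.9 to 4.21 ± 0.26 CPM. Dehydration and abscisic acid (ABA) genes fell in 18 of 26 cases and rose in 5 (median -0.53, adjusted p = 5.9e-06; adjusted p = 0.061 with an estimated correlation). LTI78, a dehydration-induced gene, dropped from 71.2 ± 0.94 to 41.8 ± 0.3 CPM. Anthocyanin genes fell in 8 of 15 cases and rose in 3 (median -0.35, adjusted p = 0.0043; adjusted p = 0.054 with an estimated correlation). Senescence genes had a median of 0.06 and a mean of -0.42, with the test pointing down (adjusted p = 0.0015; adjusted p = 0.054 with an estimated correlation). That call ended without the low-count filter (adjusted p = 0.27).

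Chaperone genes of the chloroplast rose in 13 of 14 cases in WT under Zn (median 0.49, adjusted p = 1.5e-16), with CR88, a chloroplast HSP90, going from 259 ± 2.1 to 427 ± 10 CPM. In mitochondria 11 of 14 chaperone and protease genes rose (adjusted p = 5.6e-05; adjusted p = 0.062 with an estimated correlation), and in the ER folding list 18 of 35 rose and 1 fell (adjusted p = 0.0038; adjusted p = 0.12 with an estimated correlation). HSP70 went from 137 ± 8.3 to 311 ± 5.3 CPM (1.18 ± 0.03, adjusted p = 4.4e-51), but 8 heat-shock genes rose and 8 fell (9 fell when adjusted over the list alone). The heat-shock median was -0.12 while its test pointed up (adjusted p = 0.016, or adjusted p = 0.062 with an estimated correlation). That call ended with only the compared groups in the fit (adjusted p = 0.086) and without the low-count filter (adjusted p = 0.35). Aliphatic glucosinolate genes rose in 15 of 16 cases (median 0.51, adjusted p = 7e-15) and phosphate starvation genes in 14 of 16, with 1 fall (15 rose when adjusted over the list alone; adjusted p = 1e-08). Chlorophyll synthesis genes rose in 10 of 12 cases (adjusted p = 1.2e-05; adjusted p = 0.062 with an estimated correlation), cell division genes in 11 of 17 (12 adjusted over the list alone; adjusted p = 0.0089, and adjusted p = 0.21 with an estimated correlation). Nuclear photosynthesis genes rose in 31 of 48 cases and fell in 8 (32 rose when adjusted over the list alone; adjusted p = 0.00023; adjusted p = 0.46 with an estimated correlation). In the same libraries 87 of 88 chloroplast-encoded genes rose (median 2.57, adjusted p = 2e-54), as did 45 of 55 mitochondria-encoded genes (46 adjusted over the list alone; median 1.98, adjusted p = 8.7e-10; adjusted p = 0.14 with an estimated correlation).

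Some lists did not move as a set in WT under Zn. Pattern-triggered immunity genes rose in 13 of 35 cases and fell in 5 (adjusted p = 0.36). FRK1, an early marker of immune signalling, rose from 0.94 ± 0.29 to 2.53 ± 0.84 CPM (1.45 ± 0.29, adjusted p = 1.5e-05), and RBOHD, the oxidase that makes the immune oxidative burst, rose by 1.02 ± 0.05. EFR, the elf18 receptor, stood at 1.94 ± 0.56 CPM under Zn and 2.6 ± 0.16 CPM under control (adjusted p = 0.17; -0.7, adjusted p = 0.045 without WT Zn replicate 2), and BIP3, a marker of ER stress, at 0.341 ± 0.15 and 0.71 ± 0.026 CPM (adjusted p = 0.12). AOX1A, the alternative oxidase of mitochondria, fell by 0.21 ± 0.06 (adjusted p = 0.0015), and ZIP4, a zinc transporter induced by zinc shortage, by 1.1 ± 0.24 (adjusted p = 8.4e-05). The mitochondrial stress list (5 of 17 rose, 7 fell, adjusted p = 0.6), proteasome subunits (2 of 13 rose, 1 fell, none fell when adjusted over the list alone, adjusted p = 1), iron storage (1 of 7 rose, 5 fell, adjusted p = 0.21), ethylene (8 of 19 rose, 2 fell, adjusted p = 0.14) and antioxidant genes (8 of 23 rose, 10 fell, adjusted p = 0.37) did not pass. Nor did camalexin and indole glucosinolate genes (5 of 11 rose, 5 fell, adjusted p = 0.84), root markers (7 of 19 rose, 3 fell, adjusted p = 0.15), floral markers (1 of 3 rose, adjusted p = 0.6) or seed storage genes (1 of 8 rose, 1 fell, adjusted p = 1). Across all genes tested, 5221 were higher and 4720 lower under Zn in WT, of which 503 and 514 changed by a log2 of at least 1.

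In uggt2, Zn again raised the iron-deficiency genes, 24 of 26 (median 1.5, adjusted p = 2.3e-52), and IRT1 reached 108 ± 1.4 CPM from 15.3 ± 1.6 CPM (2.82 ± 0.07). The rise of IRT1 was smaller than in WT by 1.77 ± 0.12 (interaction, adjusted p = 2.2e-23), starting from a higher control level. All but 1 of 16 phosphate starvation genes rose (median 0.83, adjusted p = 9.2e-31), as did 12 aliphatic glucosinolate genes of 16 (adjusted p = 1.5e-08), and zinc export and chelation genes rose in 11 of 17 cases and fell in 2 (adjusted p = 0.0021). Seed storage genes fell in 6 of 8 cases (adjusted p = 7e-09), led by CRU3, a storage protein gene that went from 125 ± 3.4 to 1.18 ± 0.43 CPM, and OLEO1, an oil body gene (-4.97 ± 0.28). BETA-TIP fell by 4.72 ± 0.37, and the largest rises were TED7 (3.06 ± 0.26), GSTF14 (2.95 ± 0.15) and FRO2 (2.83 ± 0.10). FRK1 fell from 4.61 ± 0.31 to 1.1 ± 0.55 CPM, against its rise in WT (interaction -3.50 ± 0.38, adjusted p = 1.3e-12). Both FRK1 and most seed storage genes had started higher in uggt2 than in WT under control. AOX1A rose from 37.4 ± 1 to 59.8 ± 1.3 CPM (interaction 0.89 ± 0.08, adjusted p = 2.9e-16). Nuclear photosynthesis genes fell in 27 of 48 cases and rose in 16 (28 fell when adjusted over the list alone; adjusted p = 0.00054; adjusted p = 0.75 with an estimated correlation). Chloroplast-encoded genes rose in 27 of 88 cases and fell in 4 (24 rose when adjusted over the list alone, adjusted p = 0.23). In all, 5254 genes were higher and 4770 lower, with 522 and 554 changed by a log2 of at least 1.

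In the libraries labelled mrpl1, Zn raised all 16 phosphate starvation genes (median 1.64, adjusted p = 4.2e-231). SPX1, a phosphate sensor gene, rose from 56.6 ± 0.15 to 315 ± 9.4 CPM (2.47 ± 0.04), and IPS1 and SPX3, also induced by phosphate shortage, rose by 3.07 ± 0.08 and 3.24 ± 0.10. PAP5, a phosphatase gene, rose by 3.83 ± 0.31. The list's rise was larger than in WT for all 16 genes (interaction median 1.38, adjusted p = 3.9e-119). All 16 had started lower in mrpl1 than in WT under control. Iron-deficiency genes rose in 18 of 26 cases and fell in 2 (3 adjusted over the list alone; adjusted p = 8.1e-35), but IRT1 moved only from 17.7 ± 0.93 to 21.8 ± 0.68 CPM, a rise smaller than in WT by 4.29 ± 0.12 (interaction, adjusted p = 2e-51). Iron storage genes fell in 5 of 7 cases (6 adjusted over the list alone; adjusted p = 3.9e-08). Salicylic acid genes fell in 16 of 21 cases (median -0.94, or -0.77 with a gene at 0 set to its bound; adjusted p = 7e-07). Outside that list, PCC1, LURP1 and AIG1 had the largest falls among all genes that met the rule (-4.90 ± 0.32, -4.42 ± 0.28 and -3.13 ± 0.18). Anthocyanin genes fell in 12 of 15 cases and rose in 1 (median -1.13, adjusted p = 4.7e-22). Heat-shock genes fell in 13 of 26 cases and rose in 7 (9 rose when adjusted over the list alone, adjusted p = 9e-09), unlike the response of WT (interaction median -0.26, adjusted p = 3.6e-11). Most heat-shock genes, and IRT1, had started higher in mrpl1 than in WT under control.

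Ethylene genes rose in 13 of 19 cases in mrpl1 under Zn and fell in 1 (adjusted p = 1.1e-05), while ABA genes fell in 16 of 26 and rose in 3 (19 fell when adjusted over the list alone; adjusted p = 1.9e-08). Jasmonate genes fell in 12 of 27 and rose in 3 (4 rose when adjusted over the list alone; adjusted p = 4.5e-06). Aliphatic glucosinolate genes fell in 11 of 16 cases and rose in 3 (adjusted p = 4.2e-07), opposite to WT (interaction median -0.78, adjusted p = 6.8e-40). MYB29, a regulator of that pathway, went from 36.9 ± 1.6 to 17.5 ± 1.2 CPM. Photosynthesis genes fell in 42 of 48 cases and rose in 2 (median -0.21, adjusted p = 2.2e-13; adjusted p = 0.15 with an estimated correlation). Chloroplast-encoded genes rose in 73 of 88 cases (76 adjusted over the list alone; median 1.15, adjusted p = 2.2e-14; adjusted p = 0.23 with an estimated correlation). FRK1 stood at 1.07 ± 0.15 CPM under Zn and 0.96 ± 0.34 CPM under control (adjusted p = 0.73). Its interaction of -1.28 ± 0.43 passed (adjusted p = 0.018) but not without WT Zn replicate 3 (adjusted p = 0.13), WT control replicate 2 (0.072), mrpl1 control replicate 2 (0.052) or mrpl1 control replicate 3 (0.097). In all, 3701 genes were higher and 3594 lower, with 403 and 361 changed by a log2 of at least 1.

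Genes changed by Zn were compared between genotypes, which share no libraries. Of genes higher under Zn, 3147 were shared by WT and uggt2 where independent lists would share 1280, and of genes lower 2197 where 1050 would be. WT and mrpl1 shared 2154 higher genes (901 for independent lists) and 1825 lower genes (791). The log2 changes correlated across genes with Pearson's r of 0.448 between WT and uggt2, 0.444 between WT and mrpl1 and 0.253 between uggt2 and mrpl1, where genes are not independent replicates.

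**Figure D3:**
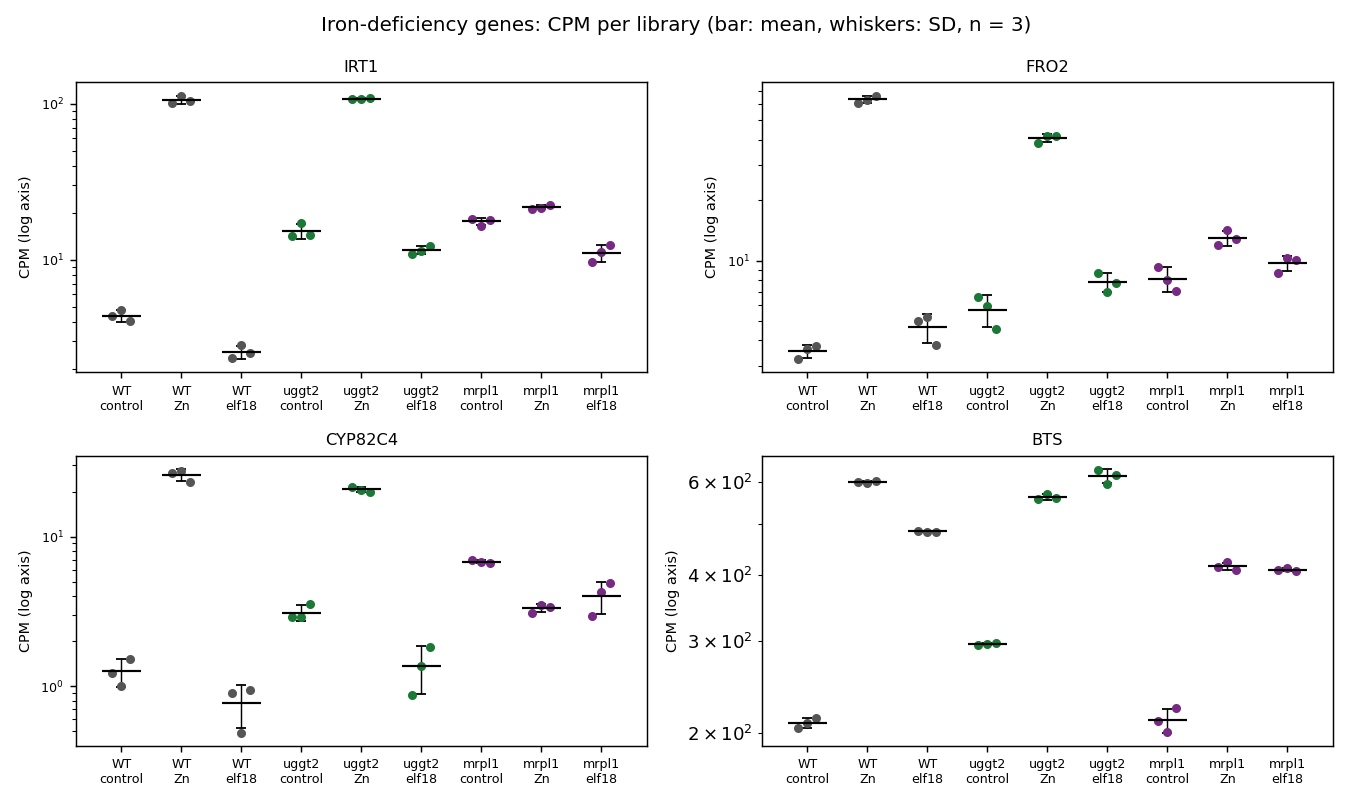
Level of the iron-deficiency genes IRT1, FRO2, CYP82C4 and BTS in CPM on a log axis in each library, by genotype and condition, with points for libraries and bars for means. IRT1 reaches 106 CPM in WT and 108 CPM in uggt2 under Zn but 21.8 CPM in mrpl1.

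Genes that differ between elf18 and control in WT bear on how plants react to a bacterial pattern. Only the elf18 label names a medium, so these differences, here and in the mutants, may include one in medium. HSP70 rose from 137 ± 8.3 to 710 ± 9.2 CPM (2.37 ± 0.03, adjusted p = 1.4e-75), and 18 of 26 heat-shock genes rose while 7 fell (median 0.80, adjusted p = 9e-19). ASG4, a gene of the MYB transcription factor family, rose from 10.2 ± 1.2 to 79 ± 2.7 CPM (2.96 ± 0.07, adjusted p = 1.6e-58), and the light-signalling regulators BBX32, BBX30 and BBX31 rose by 2.86 ± 0.10, 2.78 ± 0.16 and 2.61 ± 0.11. GIS, a trichome regulator, rose by 2.9 ± 0.16. The falls were led by TAT3 (-3.50 ± 0.32), XTH33 (-3.17 ± 0.25), MIOX2 (-2.98 ± 0.08), PAP14 (-2.73 ± 0.14), BXL1 (-2.70 ± 0.05) and EXL5 (-2.64 ± 0.08); BXL1, a cell wall xylosidase induced by sugar shortage, went from 829 ± 55 to 127 ± 10 CPM. FRK1 rose from 0.94 ± 0.29 to 3.1 ± 0.65 CPM (1.71 ± 0.27, adjusted p = 8.8e-08). Across the 35 pattern-triggered immunity genes 14 rose and 8 fell, and the set did not pass (adjusted p = 0.58). RBOHD and WRKY33 rose by 0.69 ± 0.05 and 0.79 ± 0.07, and PHI-1 fell from 29.1 ± 2 to 9 ± 1.1 CPM. EFR stood at 2.64 ± 0.61 and 2.6 ± 0.16 CPM with and without the peptide (adjusted p = 0.97).

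Iron-deficiency genes rose in 13 of 26 cases and fell in 4 in WT under elf18 (median 0.41, adjusted p = 4.6e-08). PYE, a regulator of iron homeostasis, rose from 13.7 ± 0.59 to 64.5 ± 5.1 CPM, while IRT1 fell from 4.4 ± 0.37 to 2.57 ± 0.25 CPM. Chaperones of mitochondria rose in 10 of 14 cases (11 adjusted over the list alone; adjusted p = 3.9e-05; adjusted p = 0.12 with an estimated correlation), and MTHSC70-2 by 1.17 ± 0.04. Chloroplast chaperones rose in 11 of 14 and fell in 1 (adjusted p = 2.4e-06; adjusted p = 0.068 with an estimated correlation), and ER folding genes rose in 19 of 35 (20 adjusted over the list alone; adjusted p = 0.018; adjusted p = 0.22 with an estimated correlation). Photosynthesis genes fell in 36 of 48 cases and rose in 7 (9 adjusted over the list alone; median -0.42, adjusted p = 1.9e-18; adjusted p = 0.14 with an estimated correlation). Light-harvesting LHCB2.2 dropped from 2070 ± 42 to 1150 ± 17 CPM. LOX2 and AOC2, enzymes of jasmonate synthesis, fell by 1.46 ± 0.05 and 1.91 ± 0.08, and jasmonate genes fell in 10 of 27 cases and rose in 7 (adjusted p = 0.025; adjusted p = 0.068 with an estimated correlation, and adjusted p = 0.087 without the low-count filter). Phosphate starvation genes rose in 9 of 16 cases and fell in 4 (adjusted p = 7.8e-05; adjusted p = 0.14 with an estimated correlation). Aliphatic glucosinolate genes rose in 10 of 16 and fell in 2 (3 adjusted over the list alone; adjusted p = 0.032; adjusted p = 0.4 with an estimated correlation).

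Salicylic acid genes in elf18-treated WT fell in 11 of 21 cases and rose in 3 (12 fell when adjusted over the list alone), without passing as a set (adjusted p = 0.21), and PR1 went from 3.83 ± 0.29 to 1.03 ± 0.078 CPM. Seed storage genes rose in 6 of 8 cases (adjusted p = 0.0078; adjusted p = 0.19 with an estimated correlation), CRA1 from 22.8 ± 1.6 to 115 ± 13 CPM. ABA genes rose in 11 of 26 cases and fell in 6 (7 adjusted over the list alone; adjusted p = 0.046; adjusted p = 0.49 with an estimated correlation, and adjusted p = 0.087 without the low-count filter). The senescence list had a median of 0.17 and a mean of -0.29 with a test pointing down (adjusted p = 0.0078; adjusted p = 0.13 with an estimated correlation, and adjusted p = 0.71 without the low-count filter); DIN10, a gene repressed by sugar, went from 608 ± 29 to 136 ± 2.8 CPM. AOX1A rose by 0.27 ± 0.05 (adjusted p = 2e-05). BIP3 and ZIP4 did not pass, at 0.654 ± 0.27 and 3.06 ± 0.33 CPM (adjusted p = 0.85 and adjusted p = 0.4). Chloroplast-encoded genes fell in 3 of 88 cases (none when adjusted over the list alone, adjusted p = 0.58). In all, 4575 genes were higher and 4470 lower, with 541 and 622 changed by a log2 of at least 1.

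In uggt2, elf18 raised all 16 aliphatic glucosinolate genes (median 0.66, adjusted p = 5e-15) and 16 of 17 cell division genes (median 0.40, adjusted p = 0.001; adjusted p = 0.14 with an estimated correlation). Heat-shock genes rose in 13 of 26 cases and fell in 5 (6 adjusted over the list alone; adjusted p = 1.3e-08), and HSP70 from 152 ± 3.3 to 427 ± 6.5 CPM, a smaller rise than in WT by 0.88 ± 0.05 (interaction, adjusted p = 3.1e-30). MYB111, a flavonol regulator, BBX32 and ASG4 had the largest rises (3.04 ± 0.15, 2.83 ± 0.10 and 2.61 ± 0.07), and UGT74F2, CRU3 and BT2 the largest falls (-3.42 ± 0.07, -2.99 ± 0.18 and -2.94 ± 0.05). FRK1 stood at 3.59 ± 0.7 CPM with elf18 and 4.61 ± 0.31 CPM without (adjusted p = 0.14; -0.38, adjusted p = 0.05 and just past the threshold with only the compared groups in the fit), and its response differed from that of WT (interaction -2.07 ± 0.34, adjusted p = 8.3e-07). FRK1 had started higher in uggt2 than in WT under control, and under elf18 the genotypes did not differ in it past the test. PR1 was at 0.0559 ± 0.054 CPM with elf18 and 1.27 ± 0.3 CPM without. ABA genes fell in 18 of 26 cases and rose in 4 (19 fell when adjusted over the list alone; adjusted p = 5.9e-05; adjusted p = 0.12 with an estimated correlation), and their response lay below that of WT (interaction median -0.51, adjusted p = 1.6e-20). All 88 chloroplast-encoded genes rose (median 3.26, adjusted p = 2.5e-48), as did 45 of 55 mitochondria-encoded genes (median 2.23, adjusted p = 1.1e-08; adjusted p = 0.18 with an estimated correlation). Against WT, nuclear photosynthesis genes responded more positively in 44 of 48 cases (interaction median 0.30, adjusted p = 7.3e-30), in libraries whose chloroplast share was also raised. In all, 5962 genes were higher and 5543 lower, with 661 and 992 changed by a log2 of at least 1.

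In the libraries labelled mrpl1, elf18 changed 5553 genes upward and 5598 downward, 489 and 1043 of them by a log2 of at least 1. CYP71A13, an enzyme of camalexin synthesis, rose from 2.6 ± 0.45 to 27.7 ± 1.9 CPM (3.41 ± 0.11, adjusted p = 9.2e-46), and 6 of 11 camalexin and indole glucosinolate genes rose (adjusted p = 5.6e-05). The rise of CYP71A13 exceeded that in WT by 3.03 ± 0.16 (interaction, adjusted p = 1.4e-30). BARS1 and GSTU12 rose by 5.60 ± 0.42 and 3.87 ± 0.28. BGLU35, BT2 and MLP-300B had the largest falls (-5.86 ± 0.18, -4.81 ± 0.06 and -4.18 ± 0.17). FRK1 rose from 0.96 ± 0.34 to 4.52 ± 0.46 CPM (2.24 ± 0.25, adjusted p = 5e-13). Salicylic acid genes fell in 15 of 21 cases (17 adjusted over the list alone; adjusted p = 0.00074), jasmonate genes in 16 of 27 with 4 rises (adjusted p = 2.8e-07), ABA genes in 20 of 26 with 4 rises (adjusted p = 1.2e-10) and anthocyanin genes in 12 of 15 with 1 rise (adjusted p = 1.1e-08). HSP70 was high in these plants without elf18 and fell from 737 ± 9.1 to 610 ± 16 CPM, against its rise in WT (interaction -2.65 ± 0.05, adjusted p = 2.5e-68). The heat-shock list had a median of 0.11 and a mean of -0.05 and did not pass (adjusted p = 0.29). Cell division genes rose in 16 of 17 cases (adjusted p = 0.00031; adjusted p = 0.12 with an estimated correlation).

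Between WT and uggt2, 3167 genes were higher under elf18 in both where independent lists would share 1272, and 2956 were lower in both where 1156 would be. WT and mrpl1 shared 1889 higher genes (1185 for independent lists) and 2259 lower genes (1167), while 1141 genes higher in WT were lower in mrpl1 (1195 for independent lists) and 655 lower in WT were higher in mrpl1 (1158). Opposite changes in WT and uggt2 numbered 279 (1183) and 232 (1243). Across genes, the log2 changes correlated with Pearson's r of 0.477 for WT and uggt2 and 0.389 for WT and mrpl1.

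**Figure D4:**
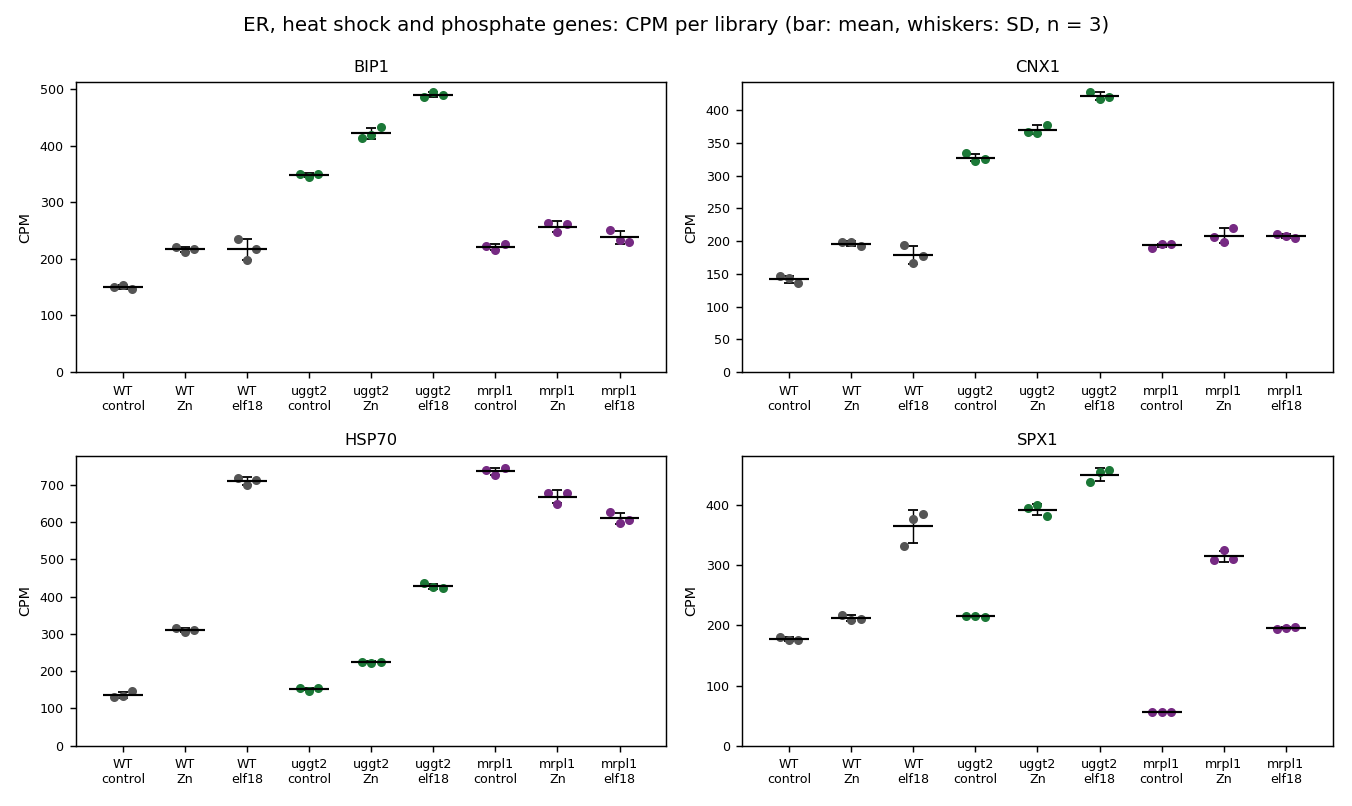
Level of BIP1, CNX1, HSP70 and SPX1 in CPM in each library, by genotype and condition, with points for libraries and bars for means. BIP1 is at 349 CPM in uggt2 and 150 CPM in WT under control, and HSP70 is at 737 CPM in mrpl1 and 137 CPM in WT under control.

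The comparison of uggt2 with WT under control asks what the reduction of a glycoprotein folding sensor does without added stress. BIP1, the main ER chaperone, stood at 349 ± 3.2 CPM in uggt2 and 150 ± 4.1 CPM in WT (1.22 ± 0.04, adjusted p = 6e-45). CNX1, the lectin chaperone calnexin, stood at 328 ± 5.7 and 142 ± 5.3 CPM (1.21 ± 0.04), and CRT1a, a calreticulin, was higher by 1.09 ± 0.04. ER folding genes were higher in 23 of 35 cases and lower in 1 (24 and 3 adjusted over the list alone; median 0.67, adjusted p = 1.3e-53). BIP3 was at 1.52 ± 0.044 and 0.71 ± 0.026 CPM (1.09 ± 0.38, adjusted p = 0.021), a call that ended without WT control replicate 1 (1.08, adjusted p = 0.057), WT control replicate 2 (1.09, adjusted p = 0.055) or uggt2 control replicate 2 (1.07, adjusted p = 0.053). Nuclear photosynthesis genes were lower in 47 of 48 cases (median -0.42, adjusted p = 2.6e-73) and all 12 chlorophyll synthesis genes were lower (adjusted p = 5.8e-11), with LHCB2.2 at 1260 ± 8 and 2070 ± 42 CPM. Chloroplast-encoded genes were lower as well (median -0.67, adjusted p = 1.8e-05, or adjusted p = 0.52 with an estimated correlation). Iron-deficiency genes were higher in 18 of 26 cases (1 lower when adjusted over the list alone; median 0.78, adjusted p = 2e-24), among them IRT1 at 15.3 ± 1.6 and 4.4 ± 0.37 CPM (1.79 ± 0.10, adjusted p = 3.3e-28) and FEP1 (1.59 ± 0.09). FER1, which encodes the iron store ferritin, was lower by 0.54 ± 0.03, and iron storage genes were lower in 3 of 7 cases and higher in 1 (4 lower when adjusted over the list alone; adjusted p = 0.0038).

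Immune genes differed as well between uggt2 and WT under control. FRK1 was at 4.61 ± 0.31 and 0.94 ± 0.29 CPM (2.28 ± 0.25, adjusted p = 1.6e-12), and pattern-triggered immunity genes were higher in 14 of 35 cases and lower in 2 (16 higher when adjusted over the list alone; adjusted p = 0.00038). Camalexin and indole glucosinolate genes were higher in 7 of 11 cases and lower in 2 (adjusted p = 3.9e-07), with CYP71A12 at 70.9 ± 3.5 and 16.2 ± 1.5 CPM. PR1 was at 1.27 ± 0.3 and 3.83 ± 0.29 CPM (-1.58 ± 0.28, adjusted p = 2e-06). Ethylene genes were higher in 8 of 19 cases and lower in 3 (9 higher when adjusted over the list alone; adjusted p = 0.0038; adjusted p = 0.056 with an estimated correlation), and ABA genes lower in 12 of 26 and higher in 3 (13 lower when adjusted over the list alone; adjusted p = 0.0067; adjusted p = 0.28 with an estimated correlation). EPR1, CRU3, BETA-TIP, ADH1, CRA1 and OLEO1 had the largest rises, of which EPR1 led with 4.71 ± 0.25. Seed storage genes were higher in 6 of 8 cases (median 2.77, adjusted p = 2.1e-15), CRU3 at 125 ± 3.4 and 5.75 ± 1.8 CPM. The list was included as a marker of seed tissue, but whether the samples held any was not tested. MRD1, FRO5 and GL22 led the lower genes (-3.35 ± 0.19, -2.72 ± 0.26 and -2.02 ± 0.15). EFR was at 3.66 ± 0.86 and 2.6 ± 0.16 CPM and did not pass (adjusted p = 0.066), but did so with only the compared groups in the fit (0.51, adjusted p = 0.042) or without uggt2 control replicate 1 (0.68, adjusted p = 0.018). AOX1A was lower by 0.44 ± 0.06. In all, 2630 genes were higher and 3386 lower, with 362 and 225 apart by a log2 of at least 1.

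Under Zn, ER folding genes were again higher in uggt2 than in WT in 23 of 35 cases and lower in 5 (median 0.62, adjusted p = 2.8e-19). BIP1 stood at 422 ± 9.7 and 217 ± 3.9 CPM. Photosynthesis genes were lower in 45 of 48 cases and higher in 1 (median -0.67, adjusted p = 5.4e-126), with LHB1B1, a light-harvesting gene, at 262 ± 5.7 and 999 ± 24 CPM, in a comparison where all 88 chloroplast-encoded genes were also lower (median -2.68, adjusted p = 1.4e-82). ABA genes were higher in 16 of 26 cases (adjusted p = 2.1e-07), phosphate starvation genes in 14 of 16 with 1 lower (adjusted p = 5.4e-18), jasmonate genes in 14 of 27 with 1 lower (adjusted p = 0.00077) and anthocyanin genes in 10 of 15 (adjusted p = 0.00013). Chloroplast chaperones were lower in 13 of 14 cases (adjusted p = 3.3e-12). IRT1 was at 108 ± 1.4 and 106 ± 6.2 CPM (adjusted p = 0.81). CYP71A12, BAM5 and GSTF14 had the largest rises (3.09 ± 0.13, 2.78 ± 0.23 and 2.03 ± 0.15), and MRD1, CRU3 and LHB1B1 the largest falls (-4.90 ± 0.27, -3.82 ± 0.37 and -1.93 ± 0.04). In all, 4486 genes were higher and 4498 lower, with 325 and 356 apart by a log2 of at least 1.

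Under elf18, uggt2 had higher ER folding genes than WT in 23 of 35 cases, with 1 lower (median 0.56, adjusted p = 2.4e-41), and BIP1 stood at 490 ± 4.5 and 217 ± 18 CPM. All 17 cell division genes (adjusted p = 1.7e-10) and all 16 aliphatic glucosinolate genes (adjusted p = 1.4e-37) were higher. ABA genes were lower in 23 of 26 cases (median -0.74, adjusted p = 4.9e-36), senescence genes in 12 of 14 with 1 higher (adjusted p = 6.1e-16) and heat-shock genes in 13 of 26 with 1 higher (adjusted p = 2.4e-06). Iron-deficiency genes were higher in 17 of 26 cases (18 higher and 2 lower when adjusted over the list alone; adjusted p = 1.8e-16), and bHLH39, IRT1 and bHLH38 were the largest rises (2.74 ± 0.15, 2.16 ± 0.13 and 1.92 ± 0.17). MRD1, CRU3 and NAP, a senescence regulator, were lower (-5.80 ± 0.29, -2.53 ± 0.18 and -2.52 ± 0.13). FRK1 did not differ past the test (3.59 ± 0.7 and 3.1 ± 0.65 CPM, adjusted p = 0.49). All 88 chloroplast-encoded genes were higher (median 2.73, adjusted p = 6.3e-101). In all, 3938 genes were higher and 4265 lower, with 324 and 287 apart by a log2 of at least 1.

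The libraries labelled mrpl1 were compared with WT under control to see what differs without treatment. Heat-shock genes were higher in 21 of 26 cases and lower in 5 (median 1.18, adjusted p = 4.1e-76). HSP70 stood at 737 ± 9.1 CPM in mrpl1 and 137 ± 8.3 CPM in WT (2.43 ± 0.03, adjusted p = 2e-76), and the co-chaperone gene ROF2 at 142 ± 1.5 and 14.7 ± 2 CPM (3.27 ± 0.06, adjusted p = 4.4e-66). The small heat-shock genes HSP17.6II, HSP17.6A, HSP23.6-MITO and HSP17.4 were higher by 4.45 ± 0.12, 3.75 ± 0.13, 3.65 ± 0.29 and 3.36 ± 0.14, though reads shared between such similar genes leave their single values uncertain. Mitochondrial chaperones and proteases were higher in 13 of 14 cases (median 0.57, adjusted p = 3.2e-13), and the mitochondrial stress list in 7 of 17 with 3 lower (8 higher when adjusted over the list alone; adjusted p = 2.6e-06). HSP23.5, a mitochondrial small heat-shock gene, stood at 46.2 ± 0.84 and 5.57 ± 0.23 CPM, and the mitochondrial stress markers AT12CYS-2 and UPOX were higher by 2.75 ± 0.16 and 2.17 ± 0.14. AOX1A was at 52.3 ± 0.54 and 50.9 ± 2 CPM (adjusted p = 0.61). Chloroplast chaperones were higher in 8 of 14 cases (adjusted p = 7.6e-16) and ER folding genes in 20 of 35 with 1 lower (21 higher when adjusted over the list alone; adjusted p = 2e-05).

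All 16 phosphate starvation genes were lower in mrpl1 than in WT under control (median -1.13, adjusted p = 1.5e-63), SPX1 at 56.6 ± 0.15 and 177 ± 3.2 CPM and SPX3 with a log2 change of -2.44 ± 0.11. All 15 anthocyanin genes were higher (median 0.94, adjusted p = 1.3e-27), as were all 17 cell division genes (median 0.67, adjusted p = 2.7e-10), with FLS1, a flavonol synthase, at 318 ± 1.6 and 166 ± 3.3 CPM. Photosynthesis genes were lower in 35 of 48 cases and higher in 5 (36 and 6 adjusted over the list alone, with adjusted p = 1.8e-27). Chloroplast-encoded genes (median -0.78, adjusted p = 1.5e-06) and mitochondria-encoded genes (median -0.59, adjusted p = 0.038) were lower as well. With an estimated correlation neither list passed (adjusted p = 0.45 and adjusted p = 0.57). Camalexin and indole glucosinolate genes were lower in 9 of 11 cases (adjusted p = 3.8e-07) and aliphatic glucosinolate genes higher in 14 of 16 with 1 lower (adjusted p = 4.3e-06). The jasmonate list was lower in 8 of 27 cases and higher in 2 (10 and 4 adjusted over the list alone; adjusted p = 0.0078). ABA and antioxidant genes were higher in 12 of 26 and 13 of 23 cases and lower in 3 and 6 (ABA 13 higher when adjusted over the list alone), each with adjusted p = 0.011, or adjusted p = 0.25 and adjusted p = 0.11 with an estimated correlation. IRT1 was at 17.7 ± 0.93 and 4.4 ± 0.37 CPM (2.01 ± 0.10, adjusted p = 2.1e-32). CYP82C4 was also among the largest rises (2.43 ± 0.19), and FRO5, MIOX2, PLA2A, ASN1 and OCT1 among the largest falls (-4.95 ± 0.35, -2.55 ± 0.07, -2.42 ± 0.18, -2.35 ± 0.06 and -2.21 ± 0.11). EFR, FRK1, PR1, BIP3 and ZIP4 did not pass (adjusted p = 0.67, adjusted p = 0.97, adjusted p = 0.77, adjusted p = 0.42 and adjusted p = 0.57). In all, 4242 genes were higher and 3888 lower, with 340 and 498 apart by a log2 of at least 1.

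Under Zn, mrpl1 had lower iron-deficiency genes than WT in 22 of 26 cases, with 1 higher (median -0.75, adjusted p = 4.6e-22), and IRT1 stood at 21.8 ± 0.68 and 106 ± 6.2 CPM (-2.28 ± 0.06, adjusted p = 1.4e-50). Root markers were lower in 10 of 19 cases and higher in 4 (median -0.14, adjusted p = 0.045; adjusted p = 0.15 with an estimated correlation). Among all genes that met the rule, TED7, NAS2 and CYP82C4 had the largest falls (-3.14 ± 0.24, -2.98 ± 0.22 and -2.95 ± 0.14). Heat-shock genes were higher in 22 of 26 cases and lower in 2 (median 0.91, adjusted p = 4.2e-24), and mitochondrial stress genes in 9 of 17 with 1 lower (10 higher when adjusted over the list alone; adjusted p = 2.6e-07), among them NDB4, an alternative dehydrogenase (3.27 ± 0.29). EPR1 and NAC044 were higher by 2.88 ± 0.26 and 2.53 ± 0.28. Photosynthesis genes were lower in 47 of 48 cases (1 higher when adjusted over the list alone; adjusted p = 5.9e-102), as were all 88 chloroplast-encoded genes (median -2.16, adjusted p = 1.1e-49), which were abundant in the WT Zn libraries. Aliphatic glucosinolate genes were lower in 14 of 16 cases (adjusted p = 1.1e-16) and phosphate starvation genes higher in 13 of 16 with 1 lower (adjusted p = 3.1e-08). EFR passed narrowly (2.89 ± 0.69 and 1.94 ± 0.56 CPM, 0.57 ± 0.24, adjusted p = 0.049). It did not pass with DESeq2 (adjusted p = 0.08), RLE size factors (0.057), organelle-encoded genes removed (0.05), no low-count filter (0.057), only the compared groups (0.077) or the replicate block (0.053), with changes of 0.55 to 0.56. Nor did EFR pass without WT Zn replicate 1 (0.52, adjusted p = 0.11), WT Zn replicate 3 (0.39, adjusted p = 0.26), mrpl1 Zn replicate 1 (0.38, adjusted p = 0.28) or mrpl1 Zn replicate 3 (0.6, adjusted p = 0.069). ZIP4, at 2.71 ± 0.69 and 1.78 ± 1.3 CPM, passed (0.70 ± 0.25, adjusted p = 0.019) but not without WT Zn replicate 2 (0.35, adjusted p = 0.32), WT Zn replicate 3 (0.54, adjusted p = 0.13) or mrpl1 Zn replicate 1 (0.48, adjusted p = 0.17), nor with only the compared groups (0.68, adjusted p = 0.1). Without WT Zn replicate 1 it was 1.34. In all, 4504 genes were higher and 4555 lower, with 387 and 602 apart by a log2 of at least 1.

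Under elf18, mrpl1 and WT differed in the largest number of genes among the 12 comparisons of a pair of groups, 6289 higher and 6450 lower, with 736 and 1088 apart by a log2 of at least 1. All 16 phosphate starvation genes were lower (median -1.18, adjusted p = 5.2e-41) and all 17 cell division genes higher (median 1.08, adjusted p = 3.4e-14). ABA genes were lower in 23 of 26 cases with 1 higher (adjusted p = 1.1e-10), jasmonate genes in 19 of 27 with 1 higher (adjusted p = 4.7e-06), ethylene genes in 11 of 19 (adjusted p = 2.2e-05) and senescence genes in 12 of 14 with 1 higher (adjusted p = 7.8e-12). Heat-shock genes were higher in 19 of 26 cases and lower in 4 (adjusted p = 1.6e-09), although HSP70 itself was at 610 ± 16 and 710 ± 9.2 CPM (-0.22 ± 0.03, adjusted p = 1.8e-09). Root markers were lower in 11 of 19 cases and higher in 4 (median -0.36, adjusted p = 0.0051; adjusted p = 0.053 with an estimated correlation), and seed storage genes lower in 6 of 8 (median -2.63, or -2.51 with a gene at 0 set to its bound; adjusted p = 0.0025; adjusted p = 0.13 with an estimated correlation). BASL, IRT1 and HSP17.4 had the largest rises (2.16 ± 0.22, 2.1 ± 0.12 and 2.08 ± 0.17), and BGLU35, MLP-300B and BT2 the largest falls (-5.42 ± 0.19, -4.26 ± 0.17 and -4.06 ± 0.06). BT2, a gene induced by low sugar and nitrate, stood at 5.89 ± 0.36 and 98.1 ± 5.8 CPM. PR1 was at 0.129 ± 0.087 and 1.03 ± 0.078 CPM (-2.93 ± 0.50, adjusted p = 3.3e-07). FRK1 was higher by 0.55 ± 0.21 (adjusted p = 0.019), a call that ended with DESeq2 (0.52, adjusted p = 0.058), or without WT elf18 replicate 2 (0.51, adjusted p = 0.064) or 3 (0.4, adjusted p = 0.14), or mrpl1 elf18 replicate 3 (0.47, adjusted p = 0.084).

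**Figure D5:**
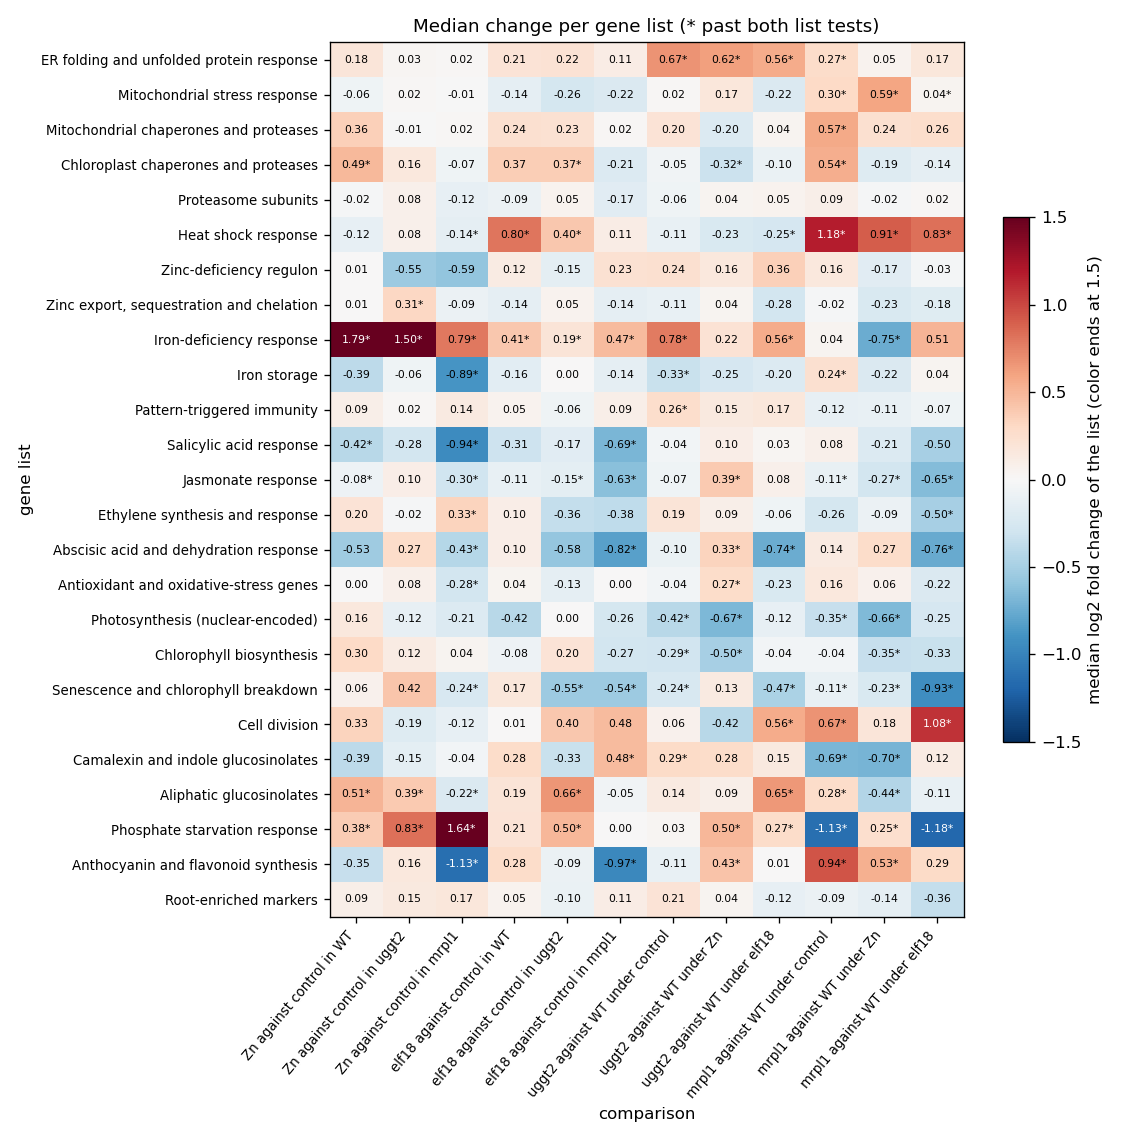
Median log2 change of the members of 25 gene lists (vertical) in the 12 comparisons of a pair of groups (horizontal), as color, with an asterisk where a list passed with both the preset and the estimated correlation. ER folding genes are raised in uggt2 against WT under control (median 0.67), and phosphate starvation genes are lower in mrpl1 against WT under control (median -1.13) and raised by Zn in mrpl1 (median 1.64).

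Interactions, which test whether a treatment changed a gene differently in a mutant and in WT, were widespread. They can arise from unlike levels under control as well as from unlike levels under treatment. For Zn they numbered 6266 in uggt2 (3294 positive, 2972 negative) and 5862 in mrpl1 (2495 and 3367), and for elf18 5399 in uggt2 (2639 and 2760) and 8720 in mrpl1 (3926 and 4794). Zn raised SIGE, a plastid sigma factor gene, more in uggt2 than in WT, by 0.91 ± 0.05 on the log2 scale (adjusted p = 7.3e-29), and ADH1, an alcohol dehydrogenase gene, went from 43.3 ± 2.4 to 15.4 ± 0.76 CPM in uggt2, with an interaction of -3.69 ± 0.13 (adjusted p = 2.9e-42). SPX1, SRG3, PS2 and PEPC1, all known from phosphate shortage, had the smallest p-values among positive interactions of Zn with mrpl1 (2.22 ± 0.05, 1.48 ± 0.05, 1.72 ± 0.06 and 1.92 ± 0.07). With elf18, HSPRO2, a gene tied to energy shortage, stood at 96.7 ± 3.8 CPM in treated uggt2 and 96.4 ± 1.1 CPM in its control, with an interaction of -1.41 ± 0.06 (adjusted p = 3e-38), and in mrpl1 it fell from 113 ± 3.4 to 30.1 ± 0.64 CPM (interaction -3.32 ± 0.06, adjusted p = 3.8e-67). BBX14, a light-signalling gene, fell from 343 ± 10 to 28.5 ± 1.5 CPM in mrpl1 (interaction -2.78 ± 0.05, adjusted p = 8.6e-65). The 4 counts rest on direct tests of each difference and not on comparing which genes passed in each genotype.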

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

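The tests of organelle transcripts, of AT2G42710 and of clock genes in this part were chosen only after the results had been seen. All values in this paragraph and the next 3 are differences between genotypes in the response to a treatment, by the interaction test, on the log2 scale. Such a difference can come from unlike levels under control. There FRK1 and most seed storage genes were higher in uggt2 than in WT, and phosphate starvation genes were lower in mrpl1. The response to Zn differed between uggt2 and WT in 6266 genes. It was more positive in uggt2 for MIPS2 (1.03), MIPS1 (0.76), COR413-PM1 (0.93), SIGE (0.91) and AOX1A (0.89). More negative responses were those of ADH1 (-3.69), FRK1 (-3.50), SUS4 (-2.86), IRT1 (-1.77), DIN10 (-1.09), CAB1 (-0.84) and AT2G42710 (-0.31). The call for AT2G42710 (adjusted p = 0.02) ended without WT control replicate 3 (-0.27, adjusted p = 0.066), uggt2 control replicate 1 (-0.26, adjusted p = 0.072) or WT Zn replicate 1 (-0.22, adjusted p = 0.13). Among lists, medians were 0.5 for ABA genes, 0.48 for phosphate starvation, 0.46 for anthocyanin, 0.2 for jasmonate and 0.2 for zinc export and chelation. They were -0.2 for chloroplast chaperones, -0.35 for mitochondrial chaperones, -0.42 for iron deficiency, -0.5 for cell division, -2.03 for chloroplast-encoded genes and -3.27 (fitted) for seed storage.

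For Zn in mrpl1 and WT, 5862 genes responded differently. Positive differences were found for SPX1 (2.22), PEPC1 (1.92), PS2 (1.72), SRG3 (1.48) and ZIP4 (0.86), and negative ones for IRT1 (-4.29), BT1 (-2), FIB (-1.78), HSP70 (-1.33) and FRK1 (-1.28). The call for ZIP4 (adjusted p = 0.038) ended with only the compared groups in the fit (0.84, adjusted p = 0.074). It also ended without WT control replicate 1 (0.8, adjusted p = 0.076), mrpl1 control replicate 3 (0.77, adjusted p = 0.086), WT Zn replicate 2 (0.51, adjusted p = 0.26), WT Zn replicate 3 (0.7, adjusted p = 0.14) or mrpl1 Zn replicate 1 (0.64, adjusted p = 0.17). Without WT Zn replicate 1 the difference was 1.51. For FRK1 the call ended without WT control replicate 2 (-1.07, adjusted p = 0.072), mrpl1 control replicate 2 (-1.19, adjusted p = 0.052), mrpl1 control replicate 3 (-1.05, adjusted p = 0.097) or WT Zn replicate 3 (-0.94, adjusted p = 0.13). Phosphate starvation genes had a median difference of 1.38. Medians were below 0 for aliphatic glucosinolates (-0.78), iron deficiency (-0.61), chloroplast chaperones (-0.46), anthocyanin (-0.37), iron storage (-0.3) and heat shock (-0.26).

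The elf18 response differed between uggt2 and WT in 5399 genes, and in 6335 without WT elf18 replicate 1. PDF1 (1.03), GER1 (1.00), TGG1 (0.90), LHCB2.3 (0.85) and AT2G42710 (0.27) responded more positively in uggt2, and BT2 (-2.1), FRK1 (-2.07), BT1 (-1.84), HSPRO2 (-1.41) and FRO7 (-1.25) more negatively. The call for AT2G42710 (adjusted p = 0.038) ended with DESeq2 (0.27, adjusted p = 0.063) and with only the compared groups in the fit (0.28, adjusted p = 0.074). It also ended without WT control replicate 1 (0.22, adjusted p = 0.14) or 2 (0.27, adjusted p = 0.062), or uggt2 control replicate 2 (0.23, adjusted p = 0.13) or 3 (0.27, adjusted p = 0.065). The same held without WT elf18 replicate 2 (0.2, adjusted p = 0.18) or 3 (0.22, adjusted p = 0.15), or uggt2 elf18 replicate 2 (0.26, adjusted p = 0.074) or 3 (0.25, adjusted p = 0.094). Positive list medians were 3.41 for chloroplast-encoded genes, 0.49 for cell division, 0.36 for aliphatic glucosinolates, 0.3 for photosynthesis and 0.23 for chlorophyll synthesis. Negative ones were -3.64 (fitted) for seed storage, -0.51 for ABA, -0.33 for ethylene, -0.23 for senescence, and -0.19 each for the mitochondrial stress, heat-shock and antioxidant lists.

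Between mrpl1 and WT, the response to elf18 differed in 8720 genes. It was more positive in mrpl1 for CYP71A13 (3.03), ERD5 (1.08), CAB3 (0.96), ZIP4 (0.74), CAB1 (0.65) and AT2G42710 (0.45). More negative were HSPRO2 (-3.32), BT1 (-2.84), PR1 (-2.83), BBX14 (-2.78), HSP70 (-2.65) and AOX1A (-0.60). The call for ZIP4 (adjusted p = 0.027) ended without WT control replicate 1 (0.66, adjusted p = 0.077), mrpl1 control replicate 3 (0.65, adjusted p = 0.076), WT elf18 replicate 3 or mrpl1 elf18 replicate 2 (each 0.65, adjusted p = 0.079). The camalexin list had a median of 0.47. ABA (-0.77), senescence (-0.7), anthocyanin (-0.68), chloroplast chaperones (-0.65), heat shock (-0.56) and jasmonate (-0.46) lists lay below 0.

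Labels were regrouped to see how many genes edgeR finds when groups are mixed. For the interaction of Zn with uggt2 the real grouping gave 6627 genes in a fit of its own 12 libraries, and the highest of the other regroupings 1775, so the real one ranked 1 of 40. The same rank of 1 of 40 was found for Zn with mrpl1 (6021, highest other 3025), elf18 with uggt2 (5014, highest other 2436) and elf18 with mrpl1 (8425, highest other 6780). Regrouped sets mix libraries that differ in genotype and treatment. These ranks therefore cannot tell an interaction apart from effects of genotype or treatment alone. For comparisons of 3 with 3 libraries, the 10 possible splits are too few for a share under 0.05. There the real split ranked 1 of 10 and edgeR gave 0 genes in the highest of the other splits. Each of those splits mixes libraries of both groups, so the difference between the groups widens the spread within them. Counts of 0 there were therefore likely in advance and cannot show what the difference is due to. Real splits gave 9636 genes for Zn in WT, 10749 in uggt2 and 7694 in mrpl1, and 7976, 11781 and 11638 for elf18 in the same genotypes. For uggt2 against WT they gave 6549 under control, 8973 under Zn and 6973 under elf18, and for mrpl1 against WT 8524, 8713 and 12031.

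Organelle-encoded transcripts were raised in the WT Zn and uggt2 elf18 libraries, where mitochondria-encoded genes rose along with chloroplast-encoded ones, in 45 of 55 cases in each, by medians of 1.98 and 2.23, although the list calls ended with an estimated correlation (adjusted p = 0.14 and adjusted p = 0.18). The medians go against a response of chloroplasts alone and are what RNA without long poly(A) tails carried into these libraries could give. A rise due to elf18 whatever the genotype did not match, since the higher median of chloroplast-encoded genes in the other genotypes was 0.25. For Zn the medians were 1.15 in mrpl1 and 0.57 in uggt2 (adjusted p = 0.23, but 0.54 and adjusted p = 0.0053 without the low-count filter, and 0.6 and adjusted p = 0.0088 with only the compared groups). So a smaller rise shared by the genotypes stayed open, while the interaction of Zn with uggt2, -2.03 (adjusted p = 2e-49; adjusted p = 0.032 with an estimated correlation), goes against an equal one.

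AT2G42710 was higher in the libraries labelled mrpl1, with 9 of 9 above the highest of the other 18. EBS1 was at 44.5 CPM or less in all uggt2 libraries and 67.2 CPM or more in all others. This goes against single libraries swapped with uggt2, and the gap in AT2G42710 against single libraries swapped between mrpl1 and WT. Had the mrpl1 and WT labels been exchanged throughout, uggt2 would share the mutant level of AT2G42710 and not that of WT. Libraries of uggt2 held 20.3 to 28.6 CPM, those labelled WT 20 to 27.8 CPM and those labelled mrpl1 44 to 63.2 CPM, which goes against such an exchange. A lost transcript of AT3G63490, the chloroplast gene that the label could also name, did not match, since its lowest log2 change was -0.21. Counts per gene cannot show whether that transcript is full-length. Other genes were taken where the reference product names a mitochondrial ribosomal protein, and 8 of these were measured. Genes not so named were not covered. The 8 genes had medians of 0.09, 0.39 and 0.52 under control, Zn and elf18 (upper quartiles 0.29, 0.45 and 0.68), against 1.08, 0.99 and 1.53 for AT2G42710. For the genes covered, this goes against a joint rise as the whole cause, and a part of it stayed open under Zn and elf18.

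Genes known to follow the day and sugar supply, BT1, BT2, BBX14, ASN1 and DIN10, differed between groups. The prediction was that harvest at another time of day moves morning and evening clock genes in opposite directions. A shift that moves both sets the same way would not show in the difference of their medians. The 95% bootstrap intervals given here resample genes, which are not independent, and do not cover the spread between libraries. For mrpl1 against WT under control the difference of their medians was 0 (interval -0.35 to 0.43). There 4 of 10 morning genes were higher and 4 lower, so moves within a set can cancel in its median. This interval goes against sets moving apart by 1 there and leaves a smaller shift open. The difference was -0.18 for Zn in WT, 0.46 for elf18 in WT and -0.06 for elf18 in mrpl1, with intervals of -0.65 to 0.24, -0.45 to 0.84 and -0.71 to 0.25. In these 3 comparisons both sets rose (medians 0.27 and 0.45, 0.85 and 0.39, 0.5 and 0.56) and no interval reached 1 in size. This goes against a shift that moves the sets apart by that much. A smaller shift, or one that raises both sets, stayed open.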

How the results depend on the processing

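All 16 counts of changed genes stayed within 1.5 times their value under every alternative, and no result that passed turned its direction. The median of seed storage genes in uggt2 against WT under Zn, which did not pass (0.14, adjusted p = 0.11), was -1.69 with only the compared groups in the fit (adjusted p = 0.0093). With an estimated correlation 142 list tests passed, against 242 with the preset. EBS1 gained a call in the interaction of Zn with uggt2 without the low-count filter (-0.26, adjusted p = 0.0045) and with only the compared groups in the fit (-0.25, adjusted p = 0.0041), and in that of elf18 with mrpl1 without the filter (-0.20, adjusted p = 0.014). With only the compared groups it also gained one for Zn in uggt2 (0.15, adjusted p = 0.028) and for mrpl1 against WT under control (0.12, adjusted p = 0.026), and lost that for elf18 in WT (0.25, adjusted p = 0.085). AT2G42710 lost its call there for Zn in WT (0.18, adjusted p = 0.068) and for elf18 with uggt2 (0.28, adjusted p = 0.074), and for the latter also with DESeq2 (0.27, adjusted p = 0.063). Leaving out 1 library changed calls for AT2G42710 in Zn in WT (0.10 to 0.24), Zn with uggt2 (-0.37 to -0.22), elf18 with uggt2 (0.20 to 0.37) and uggt2 against WT under Zn (-0.28 to -0.14). For EBS1 it did so in elf18 in WT (0.10 to 0.34), elf18 with uggt2 (0.08 to 0.32), elf18 with mrpl1 (-0.33 to -0.09) and mrpl1 against WT under elf18 (-0.21 to 0.03, from -0.11, adjusted p = 0.28). The cause was not tested.

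With the replicate block 242 list tests passed. Mitochondria-encoded genes passed there in the interaction of Zn with mrpl1 (adjusted p = 0.032, and adjusted p = 0.05 without the block), and ABA genes for elf18 in WT stood at adjusted p = 0.05 (adjusted p = 0.046 without it). Libraries with the same replicate number correlated at -0.072 to 0.292 over 36 pairs, 4 of them over 0.1, and those with other numbers at -0.224 to 0.162. In 0 of 12 comparisons were all 3 pairs over 0.1 or every library best matched to its own number, so the numbers were not taken as pairs.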

Other observations

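The clock, DUF295 and mitochondrial ribosomal protein lists in this part were chosen only after results had been seen. Clock genes rose under both treatments in WT, in morning and evening sets alike. Under elf18, 8 of 10 morning genes rose and 1 fell (median 0.85, adjusted p = 1.5e-15), as did 5 of 9 evening genes (median 0.39, adjusted p = 0.0046). In WT under Zn the medians were 0.27 (7 rose, 2 fell, adjusted p = 0.00021) and 0.45 (4 rose, 5 adjusted over the list alone, adjusted p = 0.011). In mrpl1 under Zn they were 0.33 and 0.7 (adjusted p = 7e-08 and adjusted p = 0.00017). Medians in mrpl1 under elf18 were 0.5 and 0.56 (adjusted p = 1e-06 and adjusted p = 0.023). For uggt2 they were 0.58 and 0.27 under Zn (adjusted p = 1.7e-05 and adjusted p = 0.037). Under elf18 uggt2 had 0.51 and 0.35 (adjusted p = 1.6e-08 and adjusted p = 0.022). With an estimated correlation the evening set in uggt2 under Zn did not pass (adjusted p = 0.064). A difference between control and treated plants other than the treatment itself cannot be told apart from a response to it. Why both sets rose was not tested, and a time series over a day under each treatment would be needed.

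Of 19 measured genes named DUF295 in the reference, 5 were higher and 2 lower in mrpl1 than in WT under control, 7 and 1 under Zn, and 7 and 2 under elf18. AT1G30170 stood at 0.768, 0.806 and 0.945 CPM in mrpl1 under control, Zn and elf18, and had no count in any WT library. AT5G52940 was higher in mrpl1 by 2.59, 3.25 and 3.49 under the same conditions. AT1G05540 was lower, at 3.54 against 6.48, 2.39 against 5.6 and 5.3 against 10.1 CPM. As a set the genes did not pass in mrpl1 against WT (adjusted p = 0.75, adjusted p = 0.12 and adjusted p = 0.17), and their highest median in uggt2 against WT was 0.01. The rise of some members, not shown for the set, may belong to mrpl1 alone, which RNA sequencing of further lines with a known change in AT2G42710 would test.

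Genes named as mitochondrial ribosomal proteins in the reference, other than AT2G42710, fell in 5 of 8 cases in WT under Zn (median -0.41, adjusted p = 0.029, or adjusted p = 0.088 with an estimated correlation). In mrpl1 against WT 6 of 8 were higher under elf18, without the set passing (adjusted p = 0.05).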
